A study of Homo sapiens with 6 samples.

How the data were processed

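RNA was measured by sequencing in HaCaT cells, a spontaneously immortalised human keratinocyte line, in 3 control samples and 3 samples treated with dacomitinib for 48 h. Dacomitinib is an irreversible inhibitor of the EGFR family of receptor tyrosine kinases. Per the labels, total RNA was isolated and libraries were made with a NEBNext Ultra RNA kit. The series' design text places the start of treatment at 70% confluence and attaches 0.1% DMSO to the experimental group. The vehicle of the controls and the dose of dacomitinib are not given in the sources used here. The labels do not say whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

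The deposited table gives FPKM, fragments scaled to gene length and library size, for 58735 genes in 6 sample columns, with the gene's position, length and biotype. Per the submitters' processing notes, CASAVA, fastp, HISAT2, featureCounts and DESeq2 1.20.0 were used with genome build GRCh38, with no role stated for each. All 58735 gene identifiers were found in GENCODE release 29, and 58690 had the same coordinates there. The 3 columns named with the initial of control and a number were matched to the control samples. The other 3 columns carry the letter S, which stands in no label, and were assigned to dacomitinib by elimination. Their numbers therefore only name them, and the direction of each difference below rests on this assignment.

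From the values, the deposited FPKM multiplied by the authors' gene length was a whole multiple of 1 fragment for 100% of values in every library, within a tolerance of 0.01. Fragments per gene were recovered from these steps. They summed to 14960650, 16166582 and 15405623 in the controls and to 16007328, 15171200 and 16179273 in the dacomitinib libraries. The library size in the authors' FPKM was 0.952 ± 0.00449 times the library's own sum in the controls and 1.07 ± 0.0244 times in the dacomitinib libraries (SD, n = 3). A scaling between libraries was thus applied before deposit, by a method not given in the sources used here. It bears on how many genes lie above or below the control level.

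FPKM are not counts, so the test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), for the 13748 genes with a mean FPKM of at least 1 over the 6 libraries. The threshold was a Benjamini-Hochberg adjusted p of 0.05, two-sided, with no fold limit, and differences are dacomitinib minus control. On the log2(FPKM + 1) scale the change of weakly expressed genes is understated. Errors of a log2 difference are standard errors (SE) and errors of FPKM are SD with n = 3. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so single values per library are given without a test.

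The test, the gene lists, the rule for named genes and 19 alternatives were fixed before the data were examined. There were 23 lists with 465 entries, of which 5 were matched by gene identifier because the table holds another symbol. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists, and with an estimated correlation and fry beside it. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the number of genes. That alone raises its p-values. The rule names the EGFR family receptors, the 8 protein-coding genes with the largest rise and the 8 with the largest fall whose groups did not overlap, and in each list up to 2 members with the largest rise and up to 2 with the largest fall past the threshold. It gave 88 genes. Genes named outside it are said to be so.

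The alternatives were other pseudocounts, filters, scalings (TPM, median ratio, quantile), limma settings, a block on the replicate numbers (which no label ties to shared cultures), limma-voom on the recovered fragments, leaving out each library, and the other list tests. Another 2, scaling to fragments on nuclear genes and protein-coding genes alone, were chosen after seeing the data. The procedure was tested on simulated fragments with each gene's mean in the controls, the library sizes in the authors' FPKM and the same dispersion, 0.00225, for all genes. In that simulation of the comparison of dacomitinib and control, 13158 genes were tested. Of 48 genes changed by 0.5 on the log2 scale 62.5% were recovered, of 45 changed by 1 84.4%, of 42 changed by 2 95.2% and of 42 changed by 3 100%, with 10 false calls. The median estimate of a change of 2 was 1.78. At the same simulated depth voom recovered 89.6% of the changes of 0.5, with 9 false calls. Far fewer genes were changed in the simulation than were called in the data, so these shares need not hold for the data.

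Strand is not stated for the counting, so reads of a gene and of its antisense or overlapping partner cannot be told apart. Reads of near-identical genes could likewise have been divided, which makes the values of tubulin, HLA, histone, keratin and CYP4F genes, of ALPP and S100A7, and of mitochondrial genes with nuclear copies uncertain. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.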

Results

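The series compared HaCaT keratinocytes treated for 48 h with dacomitinib with control cells, 3 samples each, to find which cell pathways differ in RNA between them. Libraries held between 14960650 and 16179273 fragments on genes. The first principal component of the tested genes held 75.6% of the variance and separated the groups. The correlation across genes of log2 values was 0.970 to 0.979 within groups and 0.870 to 0.888 between them (genes are not independent replicates), and no pair of libraries was a duplicate.

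Most measured genes of the cell division and ERK pathway lists were lower with dacomitinib, and most of the antigen presentation, antimicrobial and FOXO lists were higher. These lists and that of mitochondrially encoded mRNAs, 7 in all, passed limma's camera at the preset correlation. With an estimated correlation 0 of the 23 lists passed (3 at an unadjusted p under 0.05), and 17 passed fry. The estimated setting has few degrees of freedom with 6 libraries, so it cannot tell whether correlation between genes accounts for the calls. For the ERK list the estimated correlation, -0.0282, was below the preset 0.01. Its unadjusted camera p was still 0.00807, against 6.07e-06 at the preset. MKI67, a marker of cycling cells, fell from 87.2 ± 3.97 to 5.27 ± 0.530 FPKM, and DUSP6, a phosphatase that is a feedback target of ERK, fell from 15.1 ± 0.563 to 0.353 ± 0.180 FPKM (SD, n = 3). PIK3IP1, a negative regulator of PI3-kinase, rose from 2.83 ± 0.188 to 32.1 ± 6.31 FPKM, and CYP1A1, a xenobiotic-metabolising cytochrome P450, rose from 3.17 ± 0.818 to 38.6 ± 1.56 FPKM. EGFR, a target of the drug, rose from 74.3 ± 0.322 to 93.3 ± 0.595 FPKM.

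Of 13748 genes tested, 8271 (60.2%) differed, 3493 higher and 4778 lower with dacomitinib. Of these, 1637 differed at least 2-fold in FPKM + 1, 701 higher and 936 lower (1722 and 683 with TPM + 1). Weakly expressed genes can differ 2-fold in FPKM and fall short of that limit. TM7SF2, at 1.91 FPKM in controls and 4.11 with dacomitinib, had a difference of 0.82 in log2(FPKM + 1). The split depends on the scaling between libraries. With TPM, 68.0% of the calls were higher against 42.2% with the deposited scaling, and the median of all tested genes moved from -0.06 to 0.23 on the log2 scale.

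**Figure D1:**
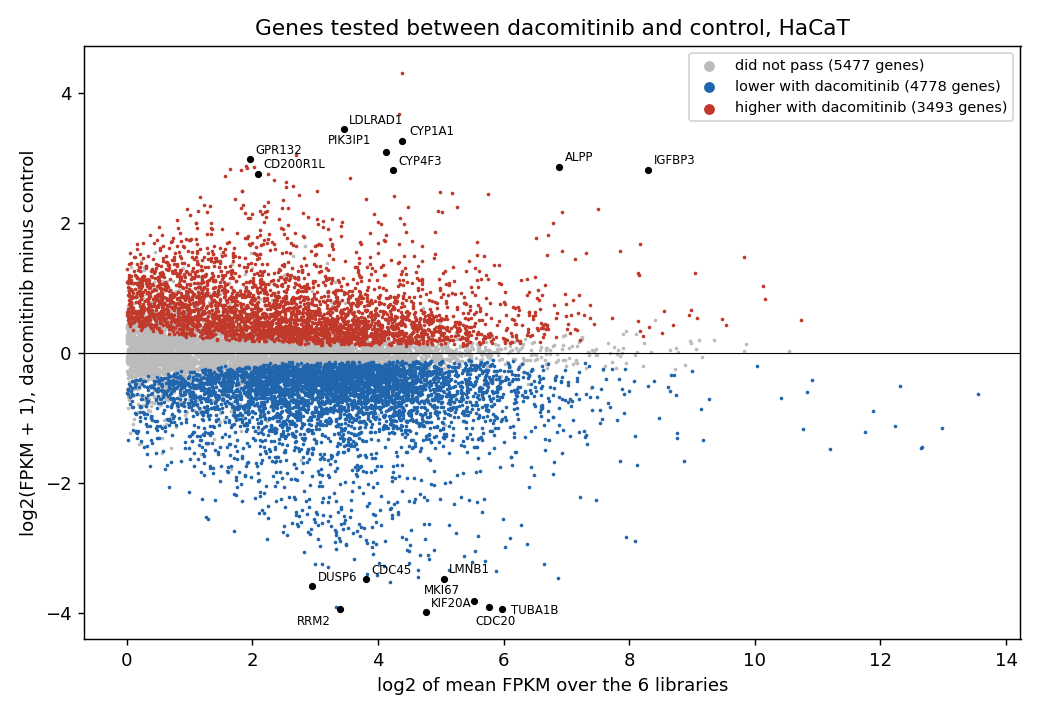
Each point is 1 of the 13748 genes tested, with the log2 of its mean FPKM over the 6 libraries on the horizontal axis and its difference in log2(FPKM + 1), dacomitinib minus control, on the vertical axis. The 4778 lower genes reach -3.98 (KIF20A), and the 16 labelled protein-coding genes are those with the largest rises and falls without overlap between groups.

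Ranked by the difference in log2(FPKM + 1), the 8 largest falls among protein-coding genes were in KIF20A, RRM2, TUBA1B, CDC20, MKI67, DUSP6, CDC45 and LMNB1. KIF20A, a mitotic kinesin (ENSG00000112984, chromosome 5, 138178719 to 138187715, GRCh38), fell from 51.8 ± 0.759 to 2.34 ± 0.187 FPKM, a log2 difference of -3.98 (SE 0.05, adjusted p = 2.90e-07). RRM2, a subunit of ribonucleotide reductase (ENSG00000171848, chromosome 2, 10120698 to 10131419), fell from 20.7 ± 2.03 to 0.415 ± 0.0617 FPKM. LMNB1, a nuclear lamin, fell from 61.4 ± 1.92 to 4.67 ± 0.736 FPKM. TUBA1B, an alpha-tubulin, fell from 119 ± 11.9 to 6.88 ± 0.456 FPKM.

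On the same log2(FPKM + 1) scale, the 8 largest rises were in LDLRAD1, CYP1A1, PIK3IP1, GPR132, ALPP, IGFBP3, CYP4F3 and CD200R1L. LDLRAD1 (ENSG00000203985, chromosome 1, 54007299 to 54018186) rose from 1.01 ± 0.0578 to 20.9 ± 1.93 FPKM, a log2 difference of 3.44 (SE 0.08, adjusted p = 7.53e-07). CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) rose by 3.27 (SE 0.14, adjusted p = 6.35e-06). IGFBP3, which binds insulin-like growth factors, rose from 77.2 ± 2.99 to 554 ± 71.6 FPKM. ALPP, a placental alkaline phosphatase, rose from 27.6 ± 1.77 to 209 ± 34.0 FPKM.

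**Figure D2:**
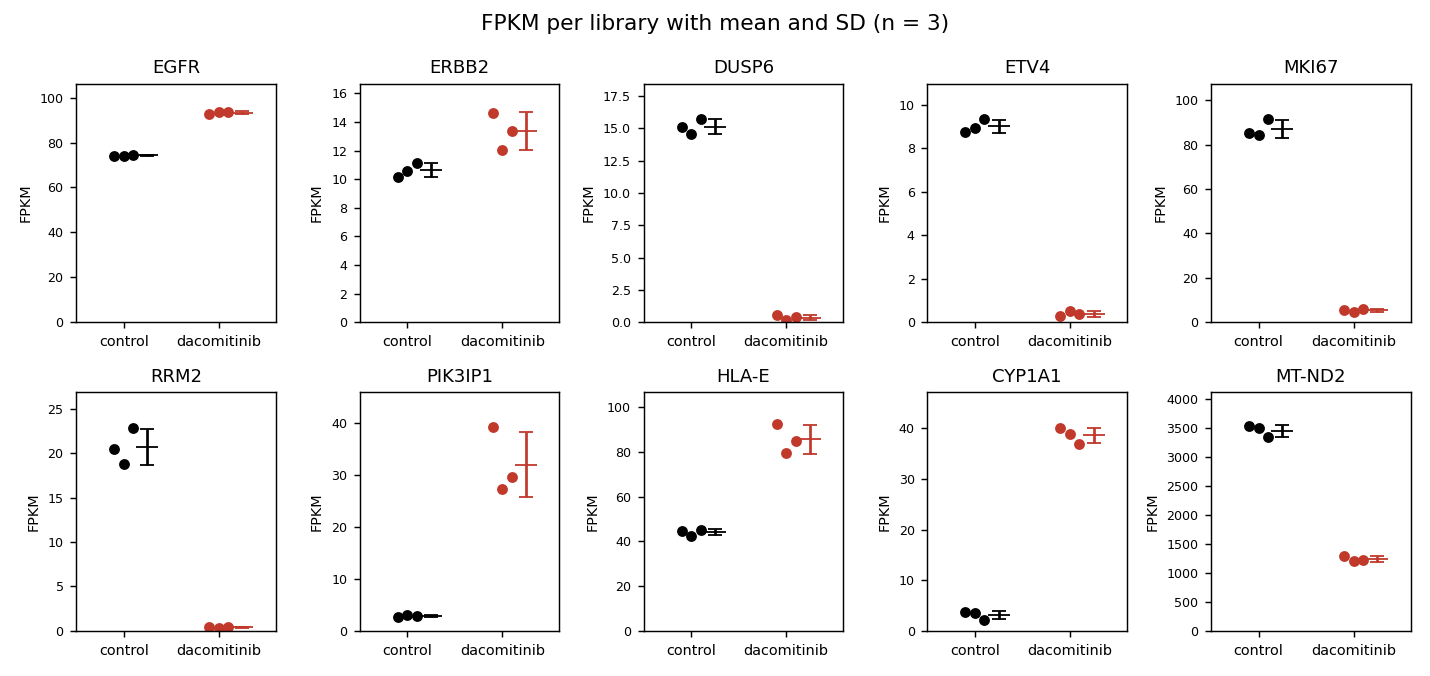
FPKM of 10 named genes in each library (points), with the mean and SD of the 3 libraries beside them. In each panel the 3 dacomitinib libraries lie apart from the 3 controls, as for DUSP6 at 15.1 FPKM in controls and 0.353 FPKM with dacomitinib.

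All 22 measured genes of the G2/M and mitosis list fell, with a median log2 difference of -3.10 (camera adjusted p = 4.69e-14; adjusted p = 0.0928 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell by 3.90 on the log2 scale (SE 0.06). Of 24 genes of the G1/S and DNA replication list, 23 fell, with a median of -2.38 (camera adjusted p = 3.04e-12; adjusted p = 0.114 with an estimated correlation). CDC45, a part of the replicative helicase, fell from 26.4 ± 0.741 to 1.48 ± 0.321 FPKM.

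Of 18 measured ERK pathway target and feedback genes, 15 fell and 1 rose, with a median of -0.95 (camera adjusted p = 3.49e-05; adjusted p = 0.0928 with an estimated correlation). ETV4, an ETS transcription factor, fell from 9.01 ± 0.308 to 0.383 ± 0.127 FPKM. DUSP5, another phosphatase of the list, rose from 7.61 ± 1.05 to 12.6 ± 1.08 FPKM.

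All 9 measured members of the EGFR family list changed, 4 up and 5 down, and the list did not pass (camera adjusted p = 0.875). Its median was -0.29, and 0.01 with TPM, where 4 rose and 3 fell. The receptors EGFR, ERBB2 and ERBB3 rose by 0.33 (SE 0.03, adjusted p = 0.000280), 0.30 (SE 0.08, adjusted p = 0.0125) and 0.33 (SE 0.05, adjusted p = 0.00187) on the log2 scale. ERBB4 was below the expression limit, with 47 fragments over the 3 controls and 156 over the 3 dacomitinib libraries. The ligand AREG fell from 8.06 ± 1.30 to 1.87 ± 0.477 FPKM and the ligand NRG1 by 1.55 on the log2 scale (SE 0.08), while the ligand BTC rose from 2.43 ± 0.497 to 4.79 ± 0.689 FPKM.

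Of 18 genes of the FOXO target and receptor feedback list, 14 rose and 1 fell, with a median of 0.53 (camera adjusted p = 1.78e-05; adjusted p = 0.358 with an estimated correlation; median 0.88 with TPM). TXNIP, an inhibitor of thioredoxin, rose from 44.0 ± 3.08 to 200 ± 5.01 FPKM. The member that fell was IRS1, at -0.29 (SE 0.08, adjusted p = 0.0209), a call lost under 7 alternatives, among them TPM (adjusted p = 0.747, with 0.0102 to 0.747 over its alternatives), leaving out control replicate 1 (adjusted p = 0.0509) or 3 (adjusted p = 0.0608), and leaving out dacomitinib replicate 1 (adjusted p = 0.0606).

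Of 18 antigen presentation genes, 14 rose and 0 fell, with a median of 0.38 (camera adjusted p = 0.000804; adjusted p = 0.358 with an estimated correlation; median 0.71 with TPM). HLA-E, a non-classical class I molecule, rose from 44.2 ± 1.38 to 85.7 ± 6.58 FPKM, and ERAP1, which trims peptides, from 21.7 ± 1.13 to 38.2 ± 1.09 FPKM. Of 6 measured antimicrobial and alarmin genes, 5 rose, with a median of 1.10 (camera adjusted p = 0.00391; adjusted p = 0.358 with an estimated correlation). The median depends on the processing, at 0.62 without a filter, 1.71 with TPM and 1.77 with voom. LCN2, an iron-siderophore binding protein, rose from 63.8 ± 6.30 to 300 ± 20.6 FPKM, and S100A7 from 1.54 ± 1.18 to 10.3 ± 2.20 FPKM.

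Of 13 mitochondrially encoded mRNAs, 12 fell, with a median of -1.12 (camera adjusted p = 0.000804; adjusted p = 0.432 with an estimated correlation; median -0.15 with quantile normalization), and the list's call was lost with that normalization (adjusted p = 0.0971, with 1.54e-06 to 0.432 over its alternatives). MT-ND2 fell from 3456 ± 102 to 1241 ± 51.4 FPKM. Fragments on mitochondrial genes made up 7.83 ± 0.389% of the controls and 4.71 ± 0.162% of the dacomitinib libraries.

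**Figure D3:**
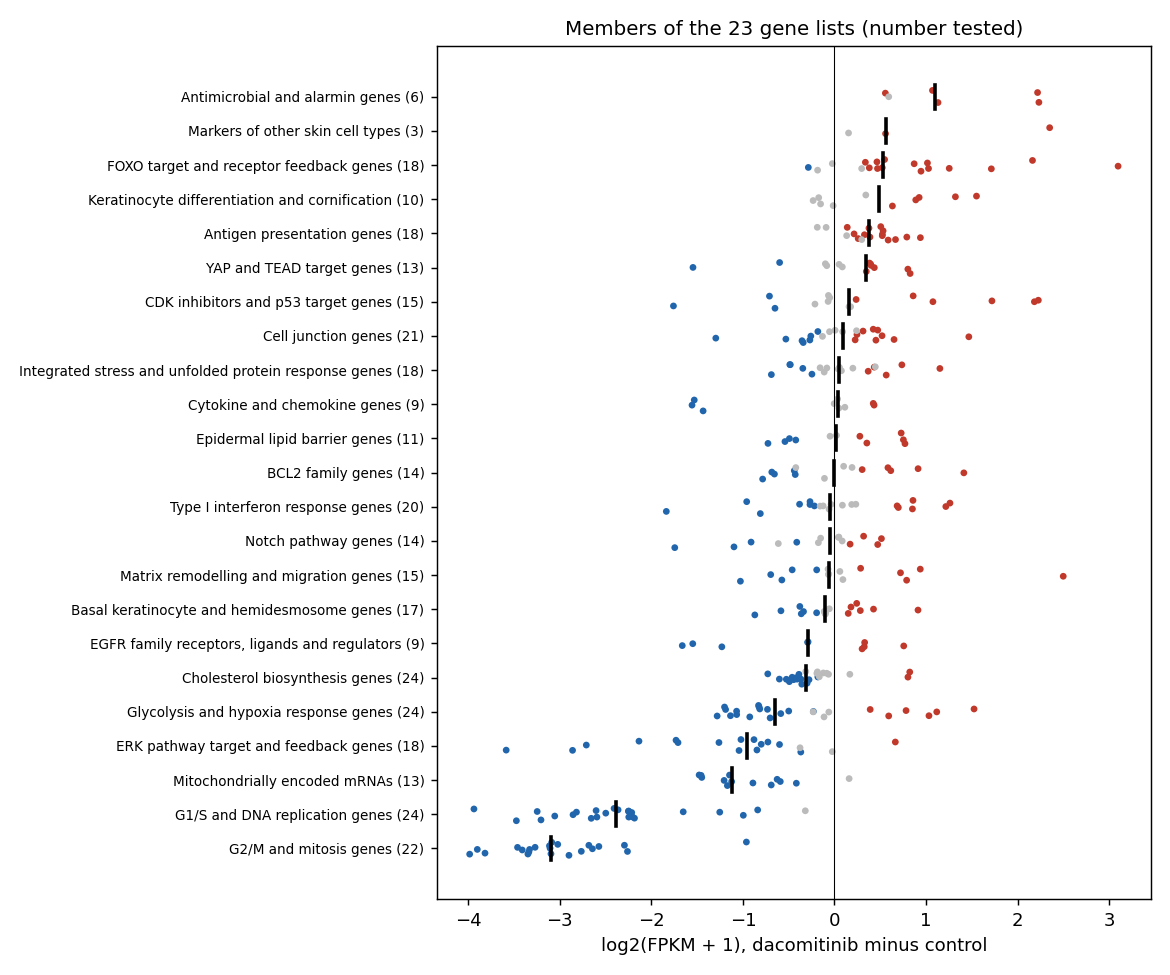
Log2 difference (dacomitinib minus control) of each measured member of the 23 lists, coloured by its call (red rose, blue fell, grey did not pass), with the list's median as a black bar. The medians run from -3.10 for G2/M and mitosis genes to 1.10 for antimicrobial and alarmin genes; the medians of the EGFR family, basal keratinocyte, interferon, BCL2, matrix and Notch lists change sign with TPM, and those of the cytokine and lipid barrier lists with quantile normalization.

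The other 15 lists did not pass camera. Counts of alternatives and ranges of p below include fry, which tests a list against no change, whereas camera compares it with the other genes. Of 10 measured keratinocyte differentiation genes, 5 rose and 0 fell (adjusted p = 0.0563; 6 and 0 with TPM), and the list passed under 8 alternatives, among them voom (adjusted p = 0.0246), quantile normalization (adjusted p = 0.0416), and leaving out control replicate 1 (adjusted p = 0.0455), dacomitinib replicate 2 (adjusted p = 0.0221) or dacomitinib replicate 3 (adjusted p = 0.0422), with 0.00167 (fry) to 0.447 over its alternatives. Among those that rose were FLG, the precursor of filaggrin, from 2.47 ± 0.147 to 9.17 ± 0.480 FPKM, and KRT4 from 20.4 ± 2.99 to 53.2 ± 13.3 FPKM. Another 17 members were below the expression limit. Of 17 basal keratinocyte and hemidesmosome genes, 6 rose and 6 fell (adjusted p = 0.950), with LAMB3, a laminin chain, up from 86.6 ± 2.92 to 164 ± 11.8 FPKM and KRT14, a basal keratin, at -0.87 (SE 0.09). With TPM 10 of them rose and 2 fell. Of 21 cell junction genes, 9 rose and 7 fell (adjusted p = 0.348), TJP3 rising by 1.47 and PKP3 falling by 1.30; 13 rose and 2 fell with TPM, and 11 and 3 with quantile normalization, where the list passed (adjusted p = 0.0400, with 0.0400 to 0.902 over its alternatives). Of 11 lipid barrier genes, 5 rose and 4 fell (adjusted p = 0.607), with UGCG up 0.77 and ELOVL1 at -0.73; with TPM 5 rose and 2 fell.

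Of 15 CDK inhibitor and p53 target genes, 6 rose and 3 fell (adjusted p = 0.138; 9 and 3 with TPM), and the list passed at a mean FPKM of at least 5 (adjusted p = 0.00119) and with fry, with 0.000884 (fry) to 0.447 over its alternatives. CDKN2B, an inhibitor of CDK4 and CDK6, rose from 10.6 ± 0.776 to 51.4 ± 0.164 FPKM, and CDKN2C, of the same family, fell from 4.56 ± 0.479 to 0.652 ± 0.238 FPKM. Of 14 BCL2 family genes, 5 rose and 5 fell (adjusted p = 0.669), with the pro-apoptotic BMF up from 0.727 ± 0.104 to 3.60 ± 0.302 FPKM and BAX down from 12.3 ± 1.24 to 7.25 ± 0.495 FPKM; with TPM 7 of them rose and 3 fell. Of 18 stress response genes, 5 rose and 5 fell (adjusted p = 0.669), with DDIT3 up 1.15 and PHGDH at -0.69; 9 rose and 2 fell with TPM, and 7 and 2 with quantile normalization.

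Of 20 interferon response genes, 6 rose and 7 fell (adjusted p = 0.669): STAT2 rose from 12.7 ± 0.332 to 30.8 ± 1.40 FPKM and OASL fell from 7.22 ± 0.486 to 1.31 ± 0.321 FPKM. With TPM, 10 rose and 3 fell. Another 8 members, named here outside the rule, were below the expression limit. Over the controls and over the dacomitinib libraries, IFI27 had 79 and 324 fragments, IFI44L 69 and 325, XAF1 43 and 282 and IRF9 133 and 222. MX1 had 110 and 104, RSAD2 129 and 117, ISG20 42 and 45 and MX2 0 and 2. Of 9 measured cytokine and chemokine genes, 2 rose and 3 fell (adjusted p = 0.950; 4 and 3 with TPM), and the median (0.03) and mean (-0.39) differ in sign. IL1A, an epidermal alarmin, fell from 13.1 ± 0.510 to 3.86 ± 1.07 FPKM. CSF1 rose from 6.24 ± 0.389 to 8.78 ± 1.49 FPKM, a call lost without control replicate 3 (adjusted p = 0.0604), without dacomitinib replicate 1 (adjusted p = 0.0570) and without dacomitinib replicate 3 (adjusted p = 0.0638), with 0.000153 to 0.0638 over its alternatives.

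Of 24 cholesterol synthesis genes, 14 fell and 2 rose (adjusted p = 0.0513), and with TPM 2 fell and 4 rose. The list passed under 5 alternatives, among them leaving out control replicate 3 (adjusted p = 0.0351) or dacomitinib replicate 2 (adjusted p = 0.0261) and a block on the replicate numbers (adjusted p = 0.0332), which do not pair the libraries, with 9.33e-05 to 0.447 over its alternatives. SQLE, squalene epoxidase, fell from 31.0 ± 0.331 to 18.4 ± 2.11 FPKM. Of 24 glycolysis and hypoxia genes, 15 fell and 6 rose (camera adjusted p = 0.0735), and with TPM 13 fell and 6 rose. The list passed under 7 alternatives, with adjusted p from 0.000312 (fry) to 0.477 over its alternatives. Among the 7 were all 5 other scalings (camera adjusted p = 0.00957 with TPM to 0.0476 with median ratio). Of the scalings, the list thus failed only with the deposited one. PGAM1 fell from 189 ± 5.79 to 77.4 ± 4.47 FPKM and EGLN3, a prolyl hydroxylase, rose from 0.849 ± 0.196 to 4.31 ± 0.513 FPKM. Of 15 matrix genes 5 rose and 5 fell (adjusted p = 0.607; 8 rose and 4 fell with TPM), MMP13 rising from 1.73 ± 0.639 to 14.7 ± 5.36 FPKM. Of 13 YAP and TEAD target genes 7 rose and 2 fell (adjusted p = 0.0828; 11 and 2 with TPM), and the list passed under 4 alternatives, among them voom (adjusted p = 0.0353, with 0.00625 for fry to 0.477 over its alternatives), with ANKRD1 falling from 2.35 ± 0.479 to 0.140 ± 0.0205 FPKM. Of 14 Notch pathway genes 4 rose and 4 fell (adjusted p = 0.950; 8 rose and 3 fell with TPM), NRARP falling by 1.74. The median of the interferon, BCL2, matrix, Notch and cytokine lists differs in sign from the list's mean or its camera direction.

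Among markers of other skin cell types, 3 of 23 passed the expression limit, and CDH5 (an endothelial cadherin) rose from 1.15 ± 0.0836 to 10.0 ± 1.39 FPKM and COL3A1 from 0.705 ± 0.0716 to 1.51 ± 0.209 FPKM (camera adjusted p = 0.0828 for the list). The list passed without the filter, which had removed the other 20 members (adjusted p = 0.0458, with 0.000172 for fry to 0.358 over its alternatives), and with fry. Of the 3, the other marker did not pass. CDH5 and COL3A1 thus differ between the same groups of libraries as the 7 lists that passed.

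Adjusted over the list alone, the counts were the same in 19 lists. In the other 4, the genes passing were 17 of 18 for the ERK list, 12 of 14 for BCL2, 17 of 21 for cell junctions and 16 of 18 for FOXO.

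Calls differed between classes of genes. Of 10622 protein-coding genes tested, 2572 rose and 4460 fell, but with TPM 4511 rose and 2528 fell. Of 1627 long non-coding genes, 656 rose and 113 fell, and with TPM 872 rose and 60 fell. NEAT1 and MALAT1, abundant nuclear RNAs chosen after their values were seen, rose from 41.2 ± 2.24 to 142 ± 10.4 FPKM and from 53.4 ± 2.75 to 154 ± 7.91 FPKM.

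**Figure D4:**
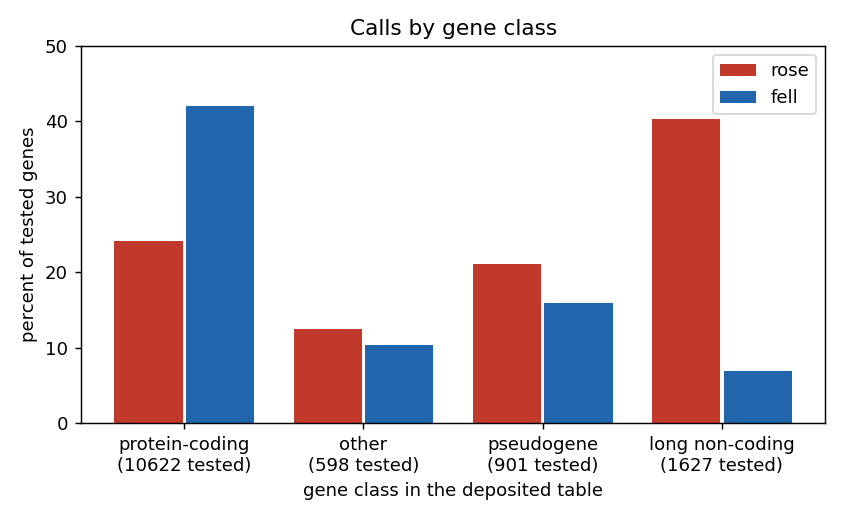
Percent of the tested genes of each class that rose (red) or fell (blue). Of long non-coding genes 40.3% rose and 6.95% fell, and of protein-coding genes 24.2% rose and 42.0% fell, a balance that turns for protein-coding genes with TPM.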

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

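The tests of the markers of other cell types below were chosen after the result was seen, and the genes named here, except CDH5 and COL3A1, after their values were seen. Genes left out of the comparison because of low expression held 1.2% of the fragments in the dacomitinib libraries and 0.775% in the controls, and the groups did not overlap. Thinned to the smallest library, 25600 ± 55.6 genes had a fragment with dacomitinib and 23779 ± 217 in controls (SD, n = 3).

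Several markers of fibroblasts and endothelial cells were higher with dacomitinib: DCN had 11 fragments over the controls and 584 over the dacomitinib libraries, VWF 153 and 628, CDH5 310 and 3089, and LUM 1 and 43. RNA of such cells would bring their abundant transcripts, but VIM, COL1A1 and COL1A2 together had 146 fragments in the controls and 107 with dacomitinib, VIM itself 3 and 0. Uniform background such as genomic DNA would raise olfactory receptor genes as much in FPKM, and their gain was 0.00674 FPKM. With 100 fragments or more, 4 fibroblast and endothelial markers were at least 2-fold higher in mean FPKM (COL3A1, DCN, VWF and CDH5). The gain of the olfactory receptor genes was 0.777% of the median gain of these 4 markers. PMEL, a melanocyte marker, was higher as well, at 106 and 261 fragments. A change of these genes within the treated HaCaT cells may account for them; this stays a hypothesis.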

How the results depend on the processing

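Genes differing, 8271 as reported, ranged from 5579 at a mean FPKM of at least 5, which tests fewer genes, to 8689 without a filter, with 7319 to 7870 when 1 library was left out. Higher calls, 3493 as reported, were 1946 at a mean FPKM of at least 5 and 5779 with TPM, and lower calls, 4778 as reported, were 2721 with TPM, where 48 genes were called in the opposite direction; the scaling moves all genes together. Genes at least 2-fold different in FPKM + 1 were 1637 as reported (701 higher, 936 lower) and 981 at a mean FPKM of at least 5. With a pseudocount of 0.1 in place of 1 they were 2339. With voom they were 2391 (1318 and 1073) and with TPM + 1 they were 2405 (1722 and 683). Median-ratio scaling gave 49.6% higher calls, quantile normalization 51.5%, voom 49.5%, and 2 settings chosen after seeing the data gave 52.2% (scaled to nuclear fragments) and 36.9% (protein-coding genes alone), against 42.2% as reported. Of the 23 lists, 7 passed camera, 0 passed with an estimated correlation (3 at an unadjusted p under 0.05) and 17 passed fry, which does not compare a list with other genes. The estimated correlation comes with degrees of freedom from the 6 libraries alone, which raises p whatever the correlation. The cause of the other shifts was not tested.

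Among named genes, 1638 of the values under alternatives kept direction and side of the threshold and 12 lost the call: IRS1 under 7 alternatives, CSF1 under 3, MT-ATP6 without a filter and COL3A1 with quantile normalization. Of the lists' values 442 kept their side, 33 newly passed and 8 were lost, 7 of these with the estimated correlation and 1 (mitochondrial mRNAs) with quantile normalization. With the replicate number as a block 7883 genes differed and 8 lists passed. Same-number libraries deviated together at correlations of 0.0267, -0.0158 and 0.0402, so the numbers do not pair the libraries. In the simulation of dacomitinib and control, with 13158 genes tested, 62.5% of changes of 0.5 were recovered by the reported fit and 89.6% by voom at the same depth. The reported fit thus missed small changes that voom recovered in that simulation, where all genes had the same dispersion and few were changed. In the data 60.2% of genes were called, which makes the adjusted threshold less strict, so the recovered shares do not carry over. In the data voom called 8593 genes and the reported fit 8271.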

Other observations

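Among tests in this part, those of the deposited scaling, of scaling by rank, of a uniform mitochondrial loss, of overlapping genes, of swapped columns, of other splits, and of the gene families other than ribosomal proteins and the nuclear respiratory chain were chosen after the result was seen, and all 10 families were picked after seeing the data. The single genes named in this part were chosen after their values were seen, except CYP1A1, KIF20A, TUBA1B, MT-ND2 and MT-ATP6, which the rule names.

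Gene families defined by symbol, 10 in all and each tested for rises and for falls against the other protein-coding genes (20 one-sided Fisher's exact tests), gave further groups. The exact test counts the genes of a family as independent, although all calls come from the same 6 libraries and members may move together. Its p-values are thus likely too small, and they do not measure the spread between samples. Families were not tested with an estimated correlation, under which 0 of the 23 lists passed, at the few degrees of freedom that 6 libraries leave. CYP1A1, KIF20A and TUBA1B, named among the largest rises and falls, were left out of their families. Nuclear genes of the respiratory chain and ATP synthase fell in 59 of 78 members and rose in 2 (exact test, adjusted p = 2.83e-08), and 49 of 78 fell with TPM. ATP5MC1, a subunit of ATP synthase, fell from 20.3 ± 2.62 to 4.87 ± 0.318 FPKM. Proteasome subunits fell in 31 of 35 members and rose in 1 (exact test, adjusted p = 1.28e-07), with PSMB2 from 41.8 ± 1.62 to 15.6 ± 1.31 FPKM, while that 1, PSMB9 of the immunoproteasome, rose from 11.2 ± 0.267 to 14.8 ± 1.61 FPKM. Kinesins fell in 15 of 22 members and rose in 4 (exact test, adjusted p = 0.0472), and tubulins fell in 5 of 8 (exact test, adjusted p = 0.515). Kinesins of the G2/M list outside the largest falls were not left out, so the kinesin result is not independent of that list.

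Lysosomal hydrolases and membrane proteins rose in 20 of 30 members and fell in 5 (exact test, adjusted p = 6.78e-06), with PSAP, the precursor of the saposins, up 1.23 on the log2 scale (SE 0.06). Histone genes went both ways, rising in 20 of 38 members and falling in 11 (exact test for rises, adjusted p = 0.000724), with HIST1H4H from 5.73 ± 0.417 to 26.3 ± 0.834 FPKM, while H2AFX fell from 83.8 ± 5.13 to 9.56 ± 2.71 FPKM. Near-identical histone genes can share reads. The hypothesis that aryl hydrocarbon receptor targets rose together, from CYP1A1, stays open: 4 of the 6 others rose (exact test, adjusted p = 0.112), with CYP1B1 from 11.3 ± 1.42 to 53.9 ± 1.99 FPKM. Cytosolic ribosomal protein genes fell in 7 of 78 members, an exact test with adjusted p = 1, and 10 of them rose (50 with TPM). Aminoacyl-tRNA synthetases (3 of 17 rose, 11 fell) and V-type ATPase subunits (2 of 17 rose, 5 fell) did not pass in either direction, and with TPM 6 and 8 of them rose and 3 and 2 fell. The medians of the families that passed kept their sign under the 5 other scalings.

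Of 1627 long non-coding genes, 656 were called higher with dacomitinib and 113 lower. Uniform background such as genomic DNA is argued against by olfactory receptor genes, whose gain in FPKM was 0.352% of the median gain of the long non-coding genes that rose. The receptor genes were themselves higher in each dacomitinib library (0.03554 to 0.0372 FPKM over the family) than in each control (0.02845 to 0.03217). Some added background is therefore not excluded. Low expression is argued against by a gap to protein-coding genes of the same FPKM of 0.358 on the log2 scale (95% interval 0.330 to 0.392), against 0.475 without matching. That interval comes from resampling the long non-coding genes, not the libraries, so it leaves out the spread between samples. Reads of overlapping genes are argued against by 289 rises and 43 falls among 604 long non-coding genes overlapping no protein-coding gene. An effect of treatment on this class of RNA may remain, as a hypothesis from the same data.

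Mitochondrially encoded mRNAs were lower with dacomitinib. A first test over all the scalings together gave no decision, because quantile normalization left the list's median only -0.166 from that of all genes, and it was then divided; its part on one factor per library was replaced, because subtracting the median of all genes removes such a factor. The scaling applied before deposit is argued against as the whole cause by the list's own median, not centred, which was -0.806 or lower with the 4 other scalings by one factor per library. The highest was with TPM, where 11 of 13 members fell while the median of all genes moved to 0.23. Under quantile normalization, where 12 of these mRNAs lie among the 30 highest values of every library and so hardly can move, scaling by rank and a real fall cannot be told apart. A fall of all transcripts of at least 200 FPKM is argued against by the 76 nuclear genes at that level, of which 19 rose and 28 fell. Their median was 0.0182 (SD 0.856), with 6 at or below the list's median of -1.12. The 12 mitochondrial mRNAs that fell had control means of 1681 (MT-ND6) to 14587 (MT-CO1) FPKM, so a fall confined to such levels was not tested. The range of these 12 members was 6.78 times the standard error of a difference between 2 members (MT-ND2 at -1.48, MT-ND1 at -0.42). A range over 12 members is wider than a difference between 2 in any case, and the counting of reads per gene can add to it. MT-ATP8 and MT-ATP6 overlap, yet had control means of 83.2 and 9430 FPKM and log2 differences of 0.16 and -1.46. Whether the loss was uniform thus stays open. MT-ATP6, MT-ATP8, MT-ND4 and MT-ND4L overlap each other in part. The fall of the nuclear respiratory genes above (adjusted p = 2.83e-08, exact test counting genes as independent) may belong with that of the mitochondrial mRNAs, a hypothesis from the same data.

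The assignment of the columns by elimination was set against a swap of the letters, under which ERK feedback genes, known to fall with EGFR inhibition, would be mostly higher in the S columns; 15 of 18 fell there. In 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, called as many genes (8271, highest other 0 with limma). The others called 120 to 254 genes at an unadjusted p under 0.05. For the lists, 6 splits, the real one included, called at least the real 7 (highest other 8), so this number does not set the real split apart. Every other split mixes the treatments unevenly. Part of the treatment difference thus stays between its groups, and the rest widens the spread within them. Such splits are therefore no null, and 10 are too few for a share under 0.05.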
